A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

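Polyadenylated RNA of diploid SK1 yeast, with and without IME4, was profiled after induction of meiosis in 8 libraries, 2 biological replicates each of WT input, WT IP, KO input and KO IP. Per the labels, NDT80 was disrupted in both genotypes; the part removed was not given in the sources used here. The deposited values are cleavage efficiencies at ACA sites, a fraction from near 0 to 1 per site and library. They are normalized per the name of the deposited table, which does not say how. The columns have nearly the same quantiles (medians over measured sites 0.636 to 0.639), as quantile normalization gives. Higher values were read as more cutting, a direction assumed from the name of the quantity and stated in none of the sources used here. The highest value of each column was shared by 3.23% to 9.80% of its measured sites, so an SD between libraries at that ceiling does not give replicate spread. The formula of the efficiency, its minimum depth and the genome build were not given in the sources used here. STAR 2.5.3a and bedtools 2.26.0 were named, with no role, per the submitters' processing notes. No read counts accompany the fractions, so the depth behind each value is unknown, and no interval or lower limit that needs it was computed.

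The table had 77601 lines for 6104 gene models. Where lines shared a position and strand (1241 positions), 1 was kept, which left 76330 sites; at 107 of those positions the lines held different values in some library. Locus names were matched to the R64 gene table, used for names only, and 5704 models matched while 400 did not. Coordinates are those of the deposited table. They are not R64 coordinates: of 5680 models matched by locus tag, 494 (8.70%) had their first listed site within 500 nt of the R64 gene. Offsets (written +696) count nt along the strand from the start of the gene model, which was constant in 6104 of 6104 models. Offsets do not skip introns, models extend beyond the coding sequence, and exon, intron and UTR were not given.

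Sites measured in all 8 libraries (17365, 22.7% of the listed sites) were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group on the fraction itself, 4 residual degrees of freedom and the empirical Bayes prior (1.72 degrees of freedom, prior SD 0.0375). Two-sided tests were adjusted by Benjamini and Hochberg over the sites of a contrast, with a threshold of 0.05. The contrasts were WT against KO in IP and in input, IP against input in WT and in KO, and the interaction. All adjusted p-values of sites are limma's. The fit gives all groups 1 variance per site, so unequal spread between groups is not modelled. With 2 libraries per group, an exact test of a single site cannot give a two-sided p below 0.333.

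For each contrast the text names up to 12 sites with lower and 6 with higher efficiency, past the threshold and with groups that do not overlap (the interaction needs the threshold only), by size of change and at most 1 per gene. Each gene list adds up to 3 further sites with the largest change in IP, and IME4, NDT80, IME1, IME2 and RME1 are always reported. The 11 lists were meiotic entry, recombination and synapsis, middle meiotic genes, m6A machinery, ribosomal proteins, glycolysis and gluconeogenesis, acetate and TCA cycle, chaperones, translation factors, ribosome biogenesis, and cell cycle and budding. They were tested with camera, with a preset correlation of 0.01 and with an estimated one. For position, each gene model was split into 5 equal parts up to its last listed site, and the last was set against the others with Fisher's exact test. The design, lists, naming rule and most alternatives were fixed before the data were examined.

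Alternatives chosen at that stage were a logit scale (offset 0.01), sites measured in at least 6 of 8 libraries, a mean efficiency of at least 0.1, quantile normalization, a robust and trended prior, only the 4 libraries of a contrast, the replicate number as a block (also nested in genotype), each library left out, and for position an adjusted p of 0.01 or a change of at least 0.1. After the data were examined, median centring, sites measured in the 4 libraries of a contrast and fitted alone, no site at 0.99 or above, camera's estimated correlation, and genes with at least 10 listed sites were added. Classes of sequence motif, the restriction to RGACA sites and centring on sites without G before ACA were not run, because no sequence of the table's build was at hand; all ACA sites were used. The quasi-binomial model was not run, because it needs counts.

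The fit was tested on simulated data for WT IP against KO IP, with 17365 sites of which 200 were changed. It recovered 0% of changes of -0.1, 18% of -0.2, 44% of -0.4 and 78% of -0.6, and 1.41% of its calls were false. The simulation had few changed sites and independent normal noise without batches. In the data 41.3% of sites passed in IP, so the simulated cutoff on the unadjusted p was stricter. Neither the recovery nor the share of false calls carries over to the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.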

Results

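Cleavage of polyadenylated RNA by MazF, a bacterial endoribonuclease that cuts before ACA and leaves the site intact when its first A carries N6-methyladenosine (m6A), was profiled in diploid budding yeast of the SK1 strain after induction of meiosis. Per the labels, both genotypes carried a disrupted NDT80, which encodes the transcription factor that drives the exit from pachytene. One genotype (WT) carried IME4, which encodes the yeast mRNA m6A methyltransferase, and the other (KO) had both copies deleted. RNA was taken before (input) and after pulldown with an antibody against m6A (IP), with 2 biological replicates in each of the 4 groups, 8 libraries in all. The deposited table gave a normalized cleavage efficiency per ACA site as a fraction. Higher values were taken to mean more cutting, which the sources used here do not state. A methylated site would be cut less often, so the comparison of WT with KO asks at which sites cutting was lower where IME4 was present. The table held 76330 distinct sites. WT input libraries measured 45366 and 62499 of them, WT IP 33343 and 43575, KO input 61501 and 62052, and KO IP 27713 and 37482. The reads behind each fraction were not given, so depth per site is unknown and no counting interval is printed. All 8 libraries measured 17365 sites in 3719 gene models, and these were tested. Over them, replicates correlated at 0.929 (WT input), 0.944 (WT IP), 0.984 (KO input) and 0.955 (KO IP). The 2 genotypes correlated at 0.767 to 0.788 in input and 0.660 to 0.681 in IP. Those correlations run across sites, which are not independent replicates.

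IME4 itself set the genotypes apart. Of its 27 listed sites, WT input measured 21 and 23, WT IP 16 and 24, while KO input measured 2 and 0 and neither KO IP library measured any. RME1, a repressor of meiotic entry, went the opposite way in input. Of its 15 listed sites, both KO inputs measured all 15, whereas the WT inputs measured 0 and 3; WT IP measured 8 in each library and KO IP measured 4 and 6. NDT80 had 3 listed sites, of which WT input measured 2 and 3, WT IP 1 and 0, KO input 0 and 1, and KO IP none. Whether these sites lie outside the disrupted part is not known. A missing value in this table does not give the level of a transcript.

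In IP, the sites with the deepest WT deficit went from nearly complete cutting in KO to almost none in WT. At the last listed site of NGR1, an RNA-binding protein gene (chromosome 2, position 638793, plus strand, 2344 nt from the start of its model), efficiency was 0.979 ± 0.029 in KO IP and 0.0060 ± 0.00059 in WT IP (mean ± SD, n = 2 libraries each), a change of -0.973 (SE 0.027, adjusted p = 4.93e-05). AHP1, which encodes a peroxiredoxin, had 0.987 ± 0.019 in KO IP and 0.0297 ± 0.0040 in WT IP at +696 (chromosome 12, position 367291). Both sites stood at 1.000 in KO IP replicate 1, the highest value of that library. Their KO IP SDs therefore do not give replicate spread. GCN2, the eIF2α kinase of the amino acid starvation response, dropped from 1.000 to 0.064 at +3069 (chromosome 4, position 1025681). HFM1, the meiotic helicase that promotes crossovers, had 0.949 in KO IP and 0.037 in WT IP at +3881 (chromosome 7, position 29035). SMC2 of condensin fell by 0.926 at +3680 and SCC2, the cohesin loader, fell by 0.924 at +2618. The other sites of this rank were in MRP51 (-0.95), MIC27 (-0.936), PIM1 (-0.932), SRL2 (-0.929), RPN9 (-0.914) and IRC22 (-0.913). In WT input the same 12 sites already stood between 0.143 and 0.720, below KO input at 0.874 to 0.989.

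**Figure D1:**
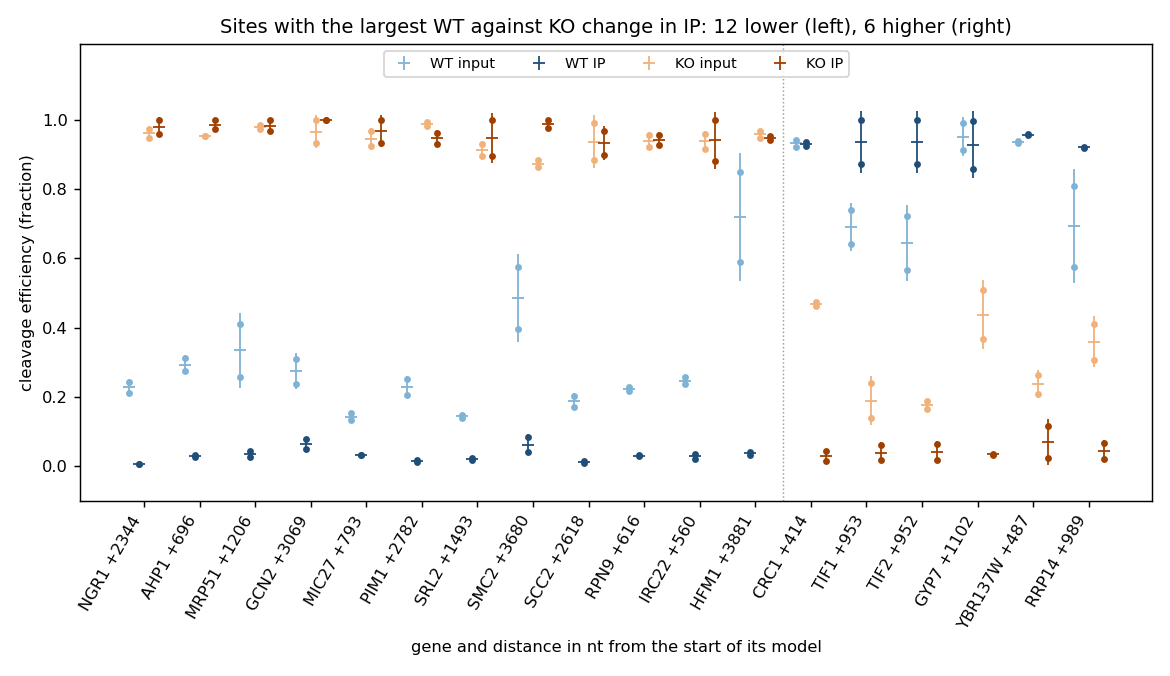
Cleavage efficiency (fraction, vertical axis) at the 18 sites with the largest WT against KO change in IP, 12 lower on the left and 6 higher on the right, in WT input, WT IP, KO input and KO IP. Points are the 2 libraries of each group, dashes their mean and bars 1 SD; NGR1 had 0.0060 in WT IP and 0.979 in KO IP.

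Other sites were cut more often in WT IP. CRC1, the mitochondrial carnitine carrier, had 0.931 ± 0.0064 in WT IP and 0.029 ± 0.021 in KO IP at +414 (chromosome 15, position 515830), a rise of 0.902 (SE 0.024, adjusted p = 4.93e-05). GYP7, a GTPase-activating protein gene, rose by 0.895 at +1102, the gene YBR137W by 0.888 at +487 and RRP14, a ribosome biogenesis gene, by 0.878 at +989. TIF1 and TIF2 rose by 0.897 and 0.895. Both encode eIF4A from near-identical sequences, so reads of the pair can be shared and their values are uncertain. Their values were identical in both WT IP libraries and in KO IP replicate 1, so the pair does not count as separate measurements.

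In limma's fit, 7176 of the 17365 sites differed between WT and KO in IP (41.3%), of which 2950 were lower in WT, in 1813 genes, and 4226 higher, in 2172 genes. Their median changes were -0.336 and 0.295. Among changes of 0.5 or more the balance was the opposite, with 823 sites lower and 470 higher. The 823 sites lay in 731 genes, of which 646 had 1 such site; HMG2, an HMG-CoA reductase gene, and UBA1, the ubiquitin-activating enzyme gene, had 4 each, the most of any gene, and were chosen after their values were seen. Over all tested sites, the 2 WT libraries lay on one side of the 2 KO libraries at 72.5%, where chance gives 33.3%. No single site can be tested exactly, because 2 against 2 libraries allow no two-sided exact p below 0.333.

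**Figure D2:**
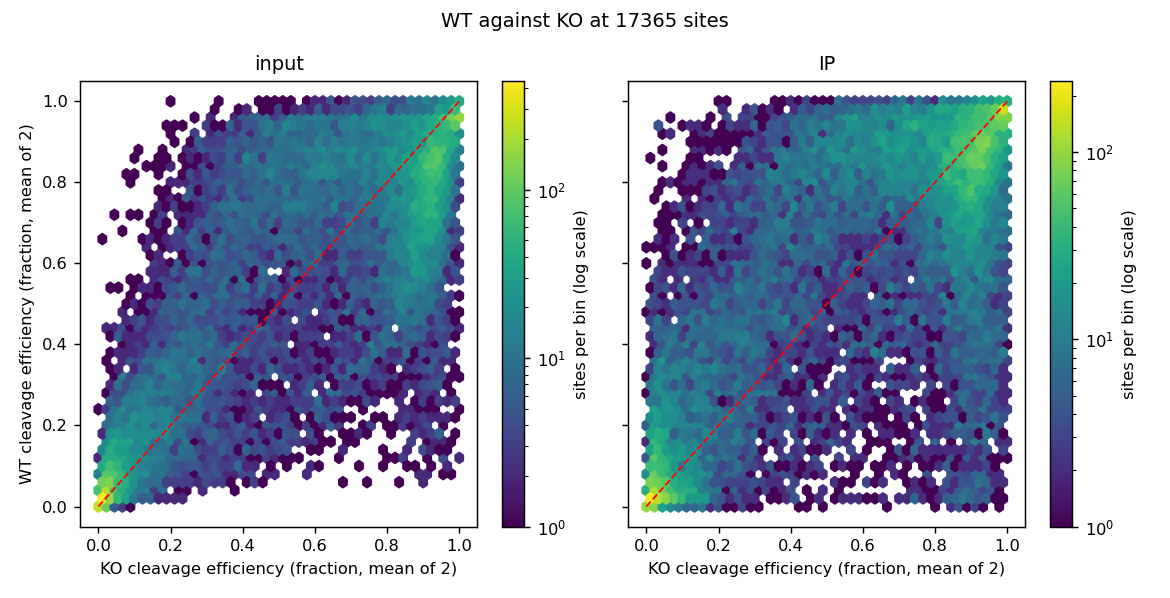
Mean cleavage efficiency (fraction) of the 2 WT libraries against that of the 2 KO libraries at the 17365 tested sites, for input (left) and IP (right). Colour gives the number of sites per bin on a log scale and the dashed line marks equal values; sites at the lower right, cut in KO and hardly cut in WT, are denser in IP, where 823 sites were lower by 0.5 or more against 280 in input.

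Genes of the recombination and synapsis list, which act in meiotic prophase, had 421 tested sites in 46 genes, of which 78 were lower and 129 higher in WT IP and 214 did not pass (81 and 136 adjusted over the list alone). RDH54, a recombination translocase, fell by 0.897 at +2919, from 0.95 ± 0.0084 in KO IP to 0.053 ± 0.023 in WT IP. SMC1 of cohesin fell by 0.881 at +3349 and MPS3, which anchors telomeres at the nuclear envelope, fell by 0.833 at +2203. The meiotic entry list had 147 sites in 18 genes, with 27 lower, 42 higher and 78 that did not pass (28 and 43 adjusted over the list alone). SIN3, a subunit of the Rpd3 histone deacetylase complex, fell by 0.884 at +4251, SUM1, the repressor of middle meiotic genes, fell by 0.759 at +3007, and RIM4, a translational repressor in meiosis, fell by 0.717 at +1211. The middle meiotic list had 17 lower, 26 higher and 73 sites that did not pass, of 116 in 23 genes (17 and 26 adjusted over the list alone). DIT1, which makes the spore wall dityrosine, fell by 0.838 at +1734. SPO1 fell by 0.821 at +2053 and rose by 0.723 at +1721. The m6A machinery list had 10 lower, 9 higher and 20 sites that did not pass, of 39 in 6 genes (11 and 11 adjusted over the list alone). VIR1, a methyltransferase complex subunit, fell by 0.425 at +1794 and rose by 0.487 at +2816, and SLZ1, another subunit, rose by 0.515 at +835.

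Genes of growth and metabolism showed both directions too. The acetate and TCA cycle list had 83 lower, 150 higher and 241 sites that did not pass, of 474 in 36 genes (90 and 153 adjusted over the list alone). ACH1, the acetyl-CoA hydrolase gene, fell by 0.889 at +154, from 1.000 in both KO IP libraries to 0.111 ± 0.036 in WT IP. YAT2, a carnitine acetyltransferase gene, fell by 0.841 at +2435 and MDH2, the cytosolic malate dehydrogenase gene, fell by 0.815 at +1506. The glycolysis and gluconeogenesis list had 19 lower, 34 higher and 78 that did not pass, of 131 in 19 genes (19 and 34 adjusted over the list alone). PCK1, the gluconeogenic PEP carboxykinase gene, fell by 0.776 at +371 and fell by 0.594 at +966. TDH3 fell by 0.686 at +1234, a value that its close paralogs make uncertain. Ribosomal protein genes had 68 lower, 114 higher and 291 that did not pass, of 473 in 116 genes (68 and 113 adjusted over the list alone). RPL25 fell by 0.833 at +965, RPP2B fell by 0.777 and RPL24A rose by 0.720. Many of these genes have a near-identical copy, so their values are uncertain. Translation factors had 34 lower, 62 higher and 142 that did not pass, of 238 in 32 genes (34 and 62 adjusted over the list alone). YEF3, translation elongation factor eEF3, fell by 0.848 at +2573, and the release factor genes SUP45 (-0.743) and SUP35 (-0.739) fell too. Ribosome biogenesis genes had 12 lower, 28 higher and 70 that did not pass, of 110 in 40 genes (12 and 28 adjusted over the list alone). NMD3 fell by 0.740, CIC1 fell by 0.667 and the helicase gene DBP10 rose by 0.712. Chaperones had 55 lower, 91 higher and 169 that did not pass, of 315 in 29 genes (61 and 95 adjusted over the list alone). The Hsp90 co-chaperone gene AHA1 fell by 0.877, HSC82 fell by 0.736, with a near-identical copy, and HSP104 rose by 0.705. The cell cycle and budding list had 12 lower, 11 higher and 45 that did not pass, of 68 in 16 genes (12 and 11 adjusted over the list alone). The septin gene CDC3 fell by 0.778 at +1335 and rose by 0.775 at +1264, and the septin gene CDC11 fell by 0.746.

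No list stood apart in its mean change, which says nothing of changes in both directions within a list. By camera with a preset correlation of 0.01, 0 of the 22 tests (11 lists in IP and in input) passed, 0 had an unadjusted p below 0.05, and adjusted p ran from 0.922 to 0.970. With an estimated correlation between sites 0 of 22 passed as well, and adjusted p ran from 0.896 to 0.964. In IP, the middle meiotic and m6A machinery lists had medians below 0 (-0.0282 and -0.00366) and means above 0 (0.00111 and 0.00555), and camera gave both as lower. In input, the recombination list had 75 lower and 97 higher sites, meiotic entry 29 and 29, middle meiotic 24 and 24, and m6A machinery 7 and 8. The acetate and TCA cycle list had 87 lower and 110 higher, glycolysis 21 and 23, ribosomal proteins 56 and 86, and translation factors 37 and 38. Ribosome biogenesis had 14 and 15, chaperones 52 and 52, and the cell cycle list 10 and 13. Adjusted over the list alone, these pairs were, in the same order, 77 and 107, 29 and 30, 25 and 25, 7 and 11, 94 and 114, 21 and 23, 56 and 85, 37 and 38, 13 and 15, 52 and 54, and 10 and 14.

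IME1, the master activator of meiotic entry, had 11 tested sites, of which 2 were lower, 4 higher and 5 did not pass in IP. At +875 (chromosome 10, position 619587, minus strand) efficiency was 0.337 ± 0.024 in WT IP and 0.873 ± 0.048 in KO IP (SD, n = 2), a change of -0.537 (SE 0.037, adjusted p = 0.000277). WT input had 0.649 there and KO input 0.815, and the interaction of genotype with IP was -0.371 (adjusted p = 0.0189). That interaction call ended with the replicate number as a block nested in genotype. IME1 rose by 0.210 at +1070, by 0.238 at +371, by 0.332 at +141 and by 0.179 at +625, and fell by 0.104 at +952. The call at +141 ended without KO IP replicate 1 (adjusted p = 0.0689), that at +952 without WT IP replicate 1 (0.051), and that at +625 without KO input replicate 1 or 2 (0.057 each) or KO IP replicate 1 (0.103) or 2 (0.0892). With only the 4 IP libraries, the calls at IME1 +141 (adjusted p = 0.0589), +625 (0.0973) and +952 (0.0683) ended too, as they did in the fit of the 4 IP libraries alone (0.0584, 0.0975 and 0.0709), and +625 ended after quantile normalization (0.103).

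IME2, the meiotic kinase gene that IME1 induces, had 16 tested sites, of which 2 were lower, 4 higher and 10 did not pass. It rose by 0.405 at +1603 (SE 0.052, adjusted p = 0.00216) and by 0.164 at +103, and fell by 0.307 at +696. Its rise at +785 ended without WT IP replicate 1 (adjusted p = 0.0581) or KO IP replicate 1 (0.0585). Its fall at +1513 ended without WT IP replicate 1 (0.0575) or 2 (0.106), KO input replicate 1 or 2 (0.0558 each) or KO IP replicate 2 (0.0809). Its rise at +1917 ended without any single library (0.0545 to 0.132) except KO IP replicate 1. IME2 +1917 also ended on the logit scale (0.0634), after quantile normalization (0.1), with only the 4 IP libraries (0.113) and in their fit alone (0.114), and +1513 ended in the last 2 of these (0.089 and 0.0903). In input, IME1 had 2 lower and 3 higher sites and 6 that did not pass, and IME2 had 1 lower and 2 higher and 13 that did not pass.

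RME1 had no site measured in all 8 libraries. A fit of the 4 IP libraries alone, over 19507 sites, was added after the data were seen. There RME1 fell by 0.605 at +1039 (chromosome 7, position 586504, minus strand; SE 0.068, adjusted p = 0.0106), from 0.992 ± 0.011 in KO IP to 0.388 ± 0.12 in WT IP. KO IP replicate 1 stood at 1.000 there, its highest value, so the KO IP SD does not give replicate spread. KO input had 0.986 ± 0.0045 at this site. The sites +848, +974 and +1145 did not pass (adjusted p 0.270, 0.170 and 0.999). Nearer the 3' end, WT IP had 0.408 ± 0.024 at +1181 and 0.128 ± 0.029 at +1283, where KO input had 0.924 ± 0.0017 and 0.736 ± 0.0062. KO IP did not measure those sites, so these differences were not tested.

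**Figure D3:**
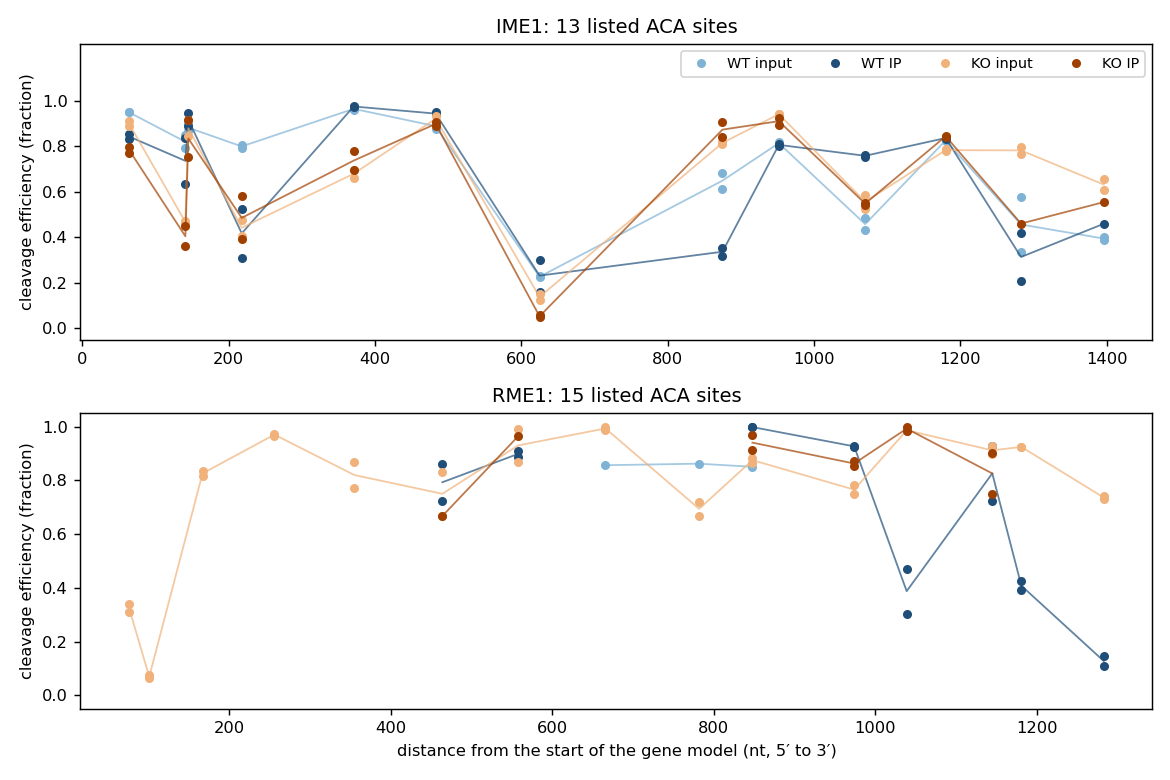
Cleavage efficiency (fraction) at the listed sites of IME1 (top) and RME1 (bottom) against distance in nt from the start of the gene model, in the 5' to 3' direction. Points are libraries coloured by group and lines join group means; WT IP had 0.337 at IME1 +875 and 0.388 at RME1 +1039, where KO IP had 0.873 and 0.992.

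In input, the question was the same without enrichment, and the 12 deepest WT deficits were in other genes, though several of them were as deep in IP (SSL2 -0.911, EPO1 -0.906). SPO24, a small sporulation gene, had 0.123 ± 0.016 in WT and 0.991 ± 0.0055 in KO at +394 (chromosome 16, position 659341), a change of -0.869 (SE 0.026, adjusted p = 0.000155). BUB3, of the spindle checkpoint, fell by 0.880 at +1209 and SSL2, a TFIIH helicase gene, fell by 0.870 at +2841. MLO50 fell by 0.905 (SE 0.082), TFA1, a TFIIE subunit gene, fell by 0.869, and AHC2 fell by 0.837. The others of this rank were YLR345W (-0.864), EPO1 (-0.831), YJR115W (-0.831) and AHA1 (-0.826), with COS5 (-0.839) and COS7 (-0.833), whose near-identical family makes their values uncertain.

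Higher cutting in WT input was seen in SSZ1, a ribosome-associated Hsp70 gene. It rose by 0.787 at +385 (SE 0.054, limma's adjusted p = 0.000522), from 0.207 to 0.993. That WT input mean lay at or near the highest values of the WT input libraries (0.992 and 0.994), so its spread is not known. FBA1, the aldolase gene, rose by 0.754, GAP1, the general amino acid permease gene, by 0.747, ADP1 by 0.756 and QNS1 by 0.721. NAM7, the nonsense-mediated decay helicase gene, rose by 0.756 (adjusted p = 0.0089), a call that ended without KO input replicate 1 (0.0529) or replicate 2 (0.0573). Of the 17365 sites, 5591 differed in limma's fit (32.2%), with 2703 lower in WT and 2888 higher. Over all tested sites the groups did not overlap at 75.5%, against 33.3% by chance. The count was 2963 without KO input replicate 1 and 2870 without KO input replicate 2.

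Sites that differed in IP also differed in input more often than independent lists would. Of the 2950 lower calls in IP, 1573 were lower in input too, where independence gives 459 (odds ratio 13.4), and of the 4226 higher calls 2241 were higher in input, where it gives 703 (odds ratio 21.8). The group means of these contrasts share no library, but IP and input of a genotype may come from the same cultures. Both tests also used the same variance per site, from the fit of all libraries together. A site with a small variance is called more readily in both contrasts. Independence is therefore not a valid baseline, and the odds ratios do not measure shared changes alone. The shared variance does not set the direction of a call. Opposite calls numbered 75 for sites lower in IP and 46 for sites higher in IP.

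Within WT, the comparison of IP with input asks whether pulldown changed the cutting seen at a site. DPS1, the aspartyl-tRNA synthetase gene, dropped from 0.993 in input to 0.048 ± 0.0060 in IP at +138 (chromosome 12, position 115291), a change of -0.945 (SE 0.043, adjusted p = 0.000508). Both input values were the highest of their library, shared by 9.80% and 8.23% of its sites, so their spread is not known. IFA38, a fatty acid elongation gene, fell by 0.828 at +509, SUI3, the eIF2 beta subunit gene, fell by 0.807 at +419, and MAE1, the malic enzyme gene, fell by 0.787 at +2006. The others of this rank were MAD3 (-0.780), of the spindle checkpoint, STB3 (-0.777), YJL132W (-0.776), SYC1 (-0.776), GTR2 (-0.769), RCF1 (-0.764), PCK1 (-0.764) and MHF2 (-0.726). NSP1, a nucleoporin gene, rose by 0.742, and GAL11, a Mediator subunit gene, rose by 0.721 at +2267, from 0.172 to 0.893. RPL32 rose by 0.671, GRX4 by 0.662, AFR1 by 0.657 and YHB1, the flavohemoglobin gene, by 0.647. In all, 3623 sites passed (20.9%), 1463 lower in IP and 2160 higher, and the groups did not overlap at 63.4% of tested sites against 33.3% by chance. On the logit scale 2109 passed, and with only the 4 WT libraries 1716. The share of lower calls was 40.4%, against 54.4% after quantile normalization and 59.4% after median centring, an alternative chosen after the data were seen.

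Within KO, fewer sites passed from input to IP than in WT, and their number depended on the libraries in the fit. NCW1, a cell wall protein gene, fell by 0.725 at +221 (SE 0.034, adjusted p = 0.00694), from 0.748 to 0.0239, and BMH1, a 14-3-3 protein gene, fell by 0.670 at +230, from 0.952 to 0.282. Smaller falls were in ATP1 (-0.524), AST2 (-0.504), PAB1 (-0.486), AIP5 (-0.473), RPS16B (-0.467), ISY1 (-0.458), CMS1 (-0.457), CRC1 (-0.440), TIR3 (-0.426) and PCD1 (-0.420). RPS27B rose by 0.693 at +201, RPL33B by 0.532, RPL16B by 0.523, YLH47 by 0.518, YHB1 by 0.513 and GPD1 by 0.463. The ribosomal protein genes among them have near-identical copies, so their values are uncertain. In limma's fit, 291 sites passed (1.68%), 102 lower and 189 higher. The groups did not overlap at 50.8% of tested sites against 33.3% by chance. The count fell to 6 without WT input replicate 1 or 2, to 67 without WT IP replicate 1 or 2, to 0 without KO input replicate 1 or 2 (1824 and 1841 sites at unadjusted p below 0.05), to 2 without KO IP replicate 1 and to 1 without KO IP replicate 2. With only the 4 KO libraries in limma, 0 sites passed and 3209 had an unadjusted p below 0.05. The share of lower calls was 35.1%, against 48.6% after quantile normalization and 57.0% after median centring.

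The interaction asks whether the change from input to IP differed between the genotypes. At LEO1, a Paf1 complex gene, WT fell from 0.915 in input to 0.197 in IP at +643 while KO went from 0.468 to 0.641, a difference of -0.891 (SE 0.077, adjusted p = 0.00758). RVS161, an amphiphysin gene, fell in WT from 0.947 to 0.222 at +616 and stood at 0.964 and 0.995 in KO, and MGM101, a mitochondrial recombination gene, fell from 0.864 to 0.150 at +128 and stood at 0.987 and 0.997 in KO. MBF1, a transcriptional coactivator gene, rose in WT from 0.280 to 0.824 at +768, where KO went from 0.695 to 0.353. In limma's fit 1345 sites passed (7.75%), 748 with a more negative change in WT and 597 with a more positive one. With the replicate number as a block 755 passed, and with that block nested in genotype 0 passed. The count was 29 without KO input replicate 1, 50 without KO input replicate 2, 860 without WT IP replicate 2, 884 without KO IP replicate 1 and 836 without KO IP replicate 2. On the logit scale it was 260, of which 221 were among the 1345, and the share of negative calls was 65.8% there against 55.6%.

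Position along the gene asks whether sites lower in WT lay near the 3' end. Each gene model was split into 5 equal parts. Of the 6555 tested sites in the last part, 1381 were lower in WT IP (21.1%), and of the 10810 in the other parts 1569 (14.5%), an odds ratio of 1.57 (Fisher's exact test, two-sided, p = 2.64e-28, adjusted over 20 tests 5.29e-27). For drops of 0.5 or more the shares were 6.53% and 3.65% (odds ratio 1.84, adjusted p = 1.33e-16). Sites higher in WT IP were fewer in the last part, 22.8% against 25.3% (odds ratio 0.870, adjusted p = 0.00057). In input, lower sites made up 18.8% and 13.6% (odds ratio 1.47), and drops of 0.5 or more 2.56% and 1.04% (odds ratio 2.51, adjusted p = 1.72e-13). From input to IP, the lower calls in WT had an odds ratio of 1.34 (adjusted p = 7.15e-07) and those in KO 0.938 (adjusted p = 0.930). Drops of 0.5 or more in WT made up 1.27% and 1.14% and did not pass (odds ratio 1.11, adjusted p = 0.671). Of the 12 named drops in IP 7 lay in the last part, and 3 of these (NGR1, AHP1 and SRL2) at the last listed site; of the 12 in input 10 lay in the last part and 1 (SSL2) at the last listed site. Measured sites leaned to the 3' end more in WT too: the share measured in the last part over that in the first was 1.99 and 1.66 in WT IP, 1.41 and 1.28 in KO IP, 1.62 and 1.24 in WT input, and 1.15 and 1.13 in KO input. The position result was not separated from this difference in coverage. The parts were counted to the last listed site of each model, and sites of a gene are not independent, so these p-values describe sites and not genes.

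**Figure D4:**
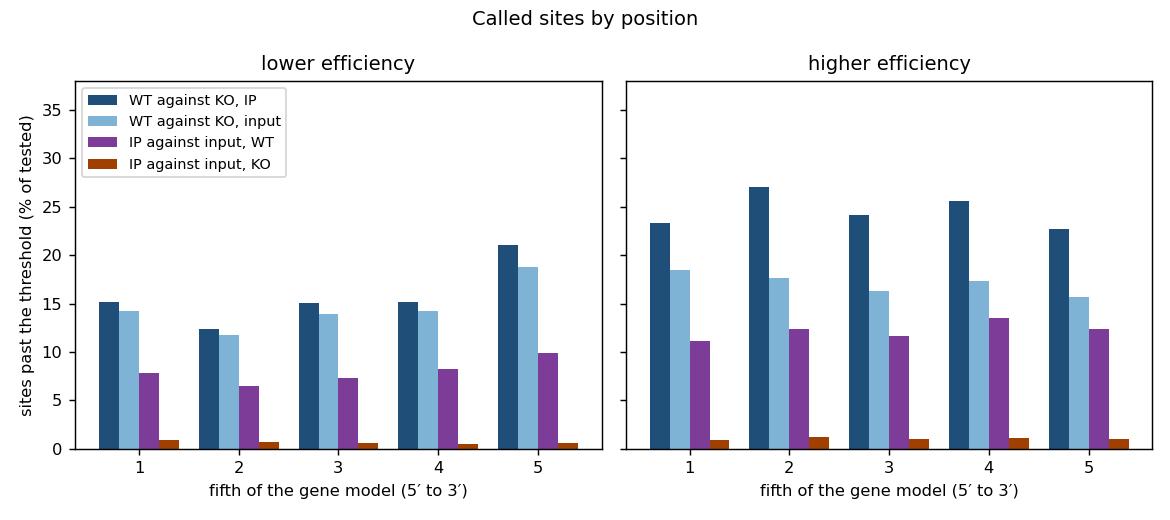
Share of tested sites past the threshold (percent) by part of the gene model, from 1 at the 5' end to 5 at the 3' end, lower on the left and higher on the right, for WT against KO in IP and in input and for IP against input in WT and in KO. Bars are percentages of the sites tested in that part; lower calls in IP made up 21.1% of part 5 and 15.1% of part 4.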

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

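Of the tests below, those of site spacing for higher sites and of antibody enrichment were written before their values were seen; those of normalization, batches, spacing for lower sites, the choice of sites on single WT input replicates and both tests of sites that dropped within WT were chosen only after the result was seen. A first set of tests had been run before the last wording: the pattern tested for antibody enrichment was reworded after its value was known, and the test of normalization replaced 2 others, a simulation (the largest 1% of simulated rises began at 0.128, against a median rise of 0.290 at the sites called higher) and rank correlations over the 14662 sites not called lower (0.826 between genotypes, 0.880 between replicates), among which drops too small to be called remain.

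The change from input to IP differed between the genotypes at 1345 sites by limma's interaction test. That test used 1 variance per site for all 4 groups, although replicates correlated at 0.929 in WT input and 0.984 in KO input. The most negative differences, WT minus KO, were at LEO1 +643 (-0.891), DPS1 +138 (-0.882), GTR2 +583 (-0.877), IFA38 +509 (-0.771), RCF1 +683 (-0.760) and RVS161 +616 (-0.756). SDH9 +1652 had -0.756, MAE1 +2006 -0.739, SGN1 +736 -0.734, YCF1 +4642 -0.731, MGM101 +128 -0.724 and ERP6 +554 -0.712. The most positive were at MBF1 +768 (0.885), GAL11 +2267 (0.854), IES2 +850 (0.711), BMH1 +230 (0.680), SPO71 +2692 (0.677) and COS8 +1250 (0.676), the last in a near-identical family and so uncertain. At BMH1 the difference came from KO, where IP stood at 0.282 and the other groups at 0.952 to 0.972. On the logit scale 5 of the 18 sites named here did not pass. With the replicate number as a block nested in genotype all 18 lost their call. Without KO input replicate 1 the count was 29 and 10 of these 18 sites did not pass; without KO input replicate 2 it was 50 and 8 did not pass.

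Within WT, 206 sites dropped by 0.5 or more from input to IP, with a median of -0.566. Pulldown that changes cutting without methylation needs a like drop in KO, where the median at the same sites was -0.0184 (95% bootstrap interval -0.0377 to -0.0116), which argues against it as the whole cause. Methylation of part of the molecules needs WT input below KO input at these sites, and the median difference was -0.0415 (interval -0.0601 to -0.0225), with 62.1% of sites below 0. That is consistent with methylation of a small share of the molecules, a hypothesis found and tested on the same data, but it was not specific to drops: the 49 sites that rose by 0.5 or more also had WT input below KO input, by a median difference of -0.292, where the choice of low WT input values adds to it.

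In input, 2703 sites were cut less often in WT than in KO. If these were methylated molecules that the antibody enriches, efficiency at sites lower by 0.25 or more would fall further from WT input to WT IP, but at 1741 such sites the median change was 0.116 (interval 0.0980 to 0.131). Choosing low WT input values pulls this up, and with sites chosen on 1 WT input replicate and measured against the other it was 0.0577 and 0.0300, against 0.0270 and 0.0234 at the other sites, so no fall was seen either way, and for the second choice hardly a rise beyond the other sites. The prediction failed for these sites as a set. Of them 35.8% fell in WT and 43.9% in KO. Choosing low WT input and high KO input values sets these shares apart by itself. With sites chosen on WT input replicate 1 or 2 alone, 40.7% and 45.9% fell from the other replicate to WT IP. No conclusion is drawn from these shares. An effect of distance to the neighbouring sites alone explained 3.61% of the variance of the change, and 89.6% of the calls remained without it, so it is not the whole cause; changes that depend on those of a neighbour are not covered by that test.

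In input, 2888 sites were cut more often in WT, which loss of methylation at the same site in KO does not predict. A normalization that keeps the order of sites, which is not known of the one used, would leave these sites in the same order, but the highest rank correlation of a WT with a KO input over them was 0.793, below the 0.867 of the less similar replicate pair; calls favour close replicates, and over the 4644 sites higher by 0.1 or more, called or not, the gap was only 0.0144 (interval 0.0016 to 0.0262), a weak argument against it as the whole cause. An effect of distance to the neighbouring sites alone explained 3.61% of the variance of the change, and 90.7% of the calls remained without it, which argues against distance alone as the whole cause. Separate batches for the genotypes cannot be told apart from the genotype: the closest WT and KO inputs correlated at 0.788 and the WT inputs at 0.929, which both explanations predict, and no label gives a batch. Differences between the strains other than IME4, and effects of its loss on RNA, stay open and untested.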

How the results depend on the processing

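Median centring, the fit of the 4 libraries of a contrast on all sites they measured, the ceiling of 0.99, camera's estimated correlation and genes with at least 10 listed sites were chosen after seeing the data; the other alternatives were planned. WT against KO in IP kept its count within 1.5 times of 7176 under all alternatives run (5693 to 10310). The 10310 came from sites measured in at least 6 of 8 libraries, where 27861 were tested. The calls themselves changed more than their count: with only the 4 IP libraries, 74.8% of the 7176 remained.

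In input the count of 5591 became 10509 with sites measured in the 4 input libraries fitted alone, where 42009 sites were tested, and ran from 2870 to 5648 with 1 library left out. The lowest were without KO input replicate 1 (2963, of which 2913 were among the 5591) and replicate 2 (2870, 2829). IP against input in WT went from 3623 to 2109 on the logit scale and to 1716 with only the 4 WT libraries. In KO the 291 became 150 with a mean efficiency of at least 0.1, 0 with only the 4 KO libraries in limma (3209 sites at unadjusted p below 0.05) and 0 with sites measured in those 4 fitted alone (4374), and ran from 0 to 67 with 1 library left out. The interaction went from 1345 to 260 on the logit scale and ran from 29 to 1277 with 1 library left out. The fits with only 4 libraries have fewer residual degrees of freedom; for the other changes the cause was not tested. A group left with 1 library is assumed to vary like the others. The fits of all libraries share that assumption, although replicates correlated at 0.929 in WT input and 0.984 in KO input.

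The labels share only replicate numbers 1 and 2. Deviations of same-numbered libraries correlated at 0.0789 for WT input with WT IP and 0.0508 for KO input with KO IP, and at -0.0168 to 0.0108 for the other 4 pairs of groups. The highest are the pairs that could share a culture. All lie below 0.1 and no pairing was assumed, but such values do not show that pairing is absent. With the replicate number as a replicate block the counts were 6843 in IP, 5284 in input, 3222 in WT, 6 in KO and 755 for the interaction. With the block nested in genotype they were 2646 in WT, 0 in KO and 0 for the interaction (limma, 2658 and 4094 sites at unadjusted p below 0.05), so all 18 named interaction sites and that of IME1 +875 had no call there. For gene lists WT vs KO 0 of 22 tests passed with the block, and for position along the gene the odds ratio was 1.53.

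For position along the gene the odds ratio ran from 1.45 to 1.63 under its alternatives, and 0 of 22 list tests passed under each of theirs. None of the named sites with a call, before or after the change of processing, reversed. Changes of sign at sites without a call in either fit were not counted. With no site at 0.99 or above, 58 of the 78 named sites in IP were left to test. All 18 named sites in KO lost their call with only the 4 KO libraries. Motif classes, the restriction to RGACA sites, centring on sites without G before ACA and the quasi-binomial model were not run. Depth limits every value to an unknown degree, since no counts were given.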

Other observations

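The test of molecules that end at the cut before an uncut site was chosen only after the result was seen; the test of coupling between neighbours was written before. The comparisons of 2 excesses, by resampling genes, were added after the values were seen. The first 2 tests belong to a first set of tests that was run before the patterns weighed above had their last wording.

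Changes at neighbouring sites were related. Between WT and KO in IP, across replicates, the changes of adjacent sites correlated at 0.239 within 30 nt and at -0.178 between 60 and 100 nt (95% interval -0.205 to -0.146), across sites, which are not independent replicates. The other contrasts had smaller values. Between WT and KO in input they were 0.0906 and -0.0502 (interval of the second -0.0678 to -0.0331). From input to IP they were 0.156 and -0.0739 in WT. In KO they were 0.0637 and -0.0111, the second with an interval that includes 0 (-0.0369 to 0.0169). At the 473 tested sites lying 60 to 200 nt before a drop of 0.5 or more in IP, the median change was 0.111, against 0.0155 at the other sites, and 45.9% were called higher, against 24.9% (permutation p = 0.0001, the smallest that the number of permutations allows). At the 289 sites after such drops the median was 0.0351, which did not pass a permutation test over sites.

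One hypothesis is that pulled-down molecules end at the cut before the uncut site. At the same 473 sites the median of WT input minus KO input was 0.0420, against 0.000126 over all tested sites. Part of the rise between the genotypes was thus present without pulldown, which this hypothesis does not cover. From WT input to WT IP these sites rose by 0.0174 more than the other sites (95% bootstrap interval 0.0035 to 0.0336), which goes with the hypothesis. In KO the same difference was -0.00853. The sites after drops had 0.0331, and the difference from the sites before them, 0.0157, had an interval that includes 0 (-0.00385 to 0.0386), so a rise on that side alone was not shown. Coupling of neighbours in the efficiency itself was taken to need as large a rise in input. Before strong drops in input the excess rise in input was 0.0519 (interval 0.0249 to 0.0832), against 0.0952 in IP (0.0669 to 0.123). The difference was 0.0433 (interval 0.00717 to 0.0766), so the prediction of an equal rise failed. The 823 drops in IP and the 280 in input were not the same set and were not matched in size. Coupling that grows with the drop could give this difference, so the test cannot decide against coupling, as the whole cause or as a part.

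Whole genes did not stand apart in the mean of their changes between the genotypes, which leaves room for neighbouring sites to change together. Over 1444 genes with at least 5 tested sites, -0.104% of the variance of the change in IP and 0.0431% of that in input lay between genes, below the highest 2.5% of shuffled values (0.851% and 1.03%). From input to IP it was 0.598% in WT (shuffled 0.881%) and 1.31% in KO, above the shuffled values.

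The sets of measured sites also differed. Of 42009 sites measured in all 4 input libraries, 3573 were measured in both WT IP libraries and in no KO IP library, and 43.3% of these lay in the last of 5 parts of the gene model, against 33.5% of all. The reverse held for 1395 sites, of which 19.7% lay in the last part. KO IP libraries measured fewer sites in all (27713 and 37482) than WT IP libraries (33343 and 43575). The counts of 3573 and 1395 were not separated from this difference in coverage.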
